A study of Mus musculus with 2 samples.

How the data were processed

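Amplicon libraries were sequenced from genomic DNA of 2 lines of mouse haploid embryonic stem cells, 1 library per line, as paired reads in sequencing lanes 3 and 4 according to the read names. The labels give the lines by title, and the series describes the samples as different cell lines, so each library was taken as its own group. Per the submitters' processing notes, reads were checked with FastQC 0.11.2, trimmed with Trimmomatic 0.36 and aligned with BWA; the BWA version, its settings and the reference sequences are not given in the sources used here. The deposited files list 1 line per aligned read end, with the construct name, start, end, read name, score and strand. The deposited score is a whole number from 0 to 60 and was read as the aligner's mapping quality, which is low when another construct of the reference fits a read nearly as well. Where constructs share most of their sequence, this score depends on how similar they are to each other, and a minimum on it can remove true reads of similar constructs. How similar the constructs of each set are was not measured, since their sequences were not used. No read sequence or base quality was used here.

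Alignment lines were counted per construct with pandas 2.3.3 under Python 3.11.15, with NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. The following choices were made before the data were examined. Alignments with a mapping quality of at least 1 were counted, a construct was called covered at 10 alignments, and evenness was measured by the Gini coefficient and by the ratio of the 90th to the 10th percentile over covered constructs. The limit for evenness was planned over both libraries together and was applied to each library instead, since a common numbering was not established. The text names the 10 constructs with the most counted alignments in each library. Constructs named outside this rule, such as those under a limit or with split pairs, were chosen after their values were seen. Alternatives were no minimum, a minimum of 20 or 30, a limit of 1 or 100 alignments, thinning of DP2 to the 9305738 counted alignments of DP1, and counting each distinct start, end and strand a single time. The single lanes, the pairs with both ends on a construct and the share of the most abundant construct were added after the data were seen.

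Shares have Wilson 95% intervals, and the Gini coefficient and percentile ratio have intervals from 1000 multinomial draws. A share of 0 is given the upper limit of 3 counts over the total. No molecular identifiers were used, so PCR copies count as separate reads. The 2 ends of a pair were also counted separately, although both mostly lay on the same construct. Except for shares of pairs, intervals and limits treat read ends as independent, so they are too narrow even for counting error. No interval covers any other error. With 23702568 and 23897664 alignments, counting error was small against the difference between lanes. A read pair was formed from the 2 lines of a read name, which held for 99.9% of the names in each library. An alignment was said to span the amplicon when it began within 10 bases of the most frequent start and ended within 10 bases of the construct's most frequent end. Bases are counted from 1 at the first base of each construct's reference sequence. The counting was tested on simulated data with as many constructs as DP1 and DP2 and 50000 simulated pairs each. The counts and the pairs in agreement were recovered exactly for 78 of 78 and for 31 of 31 constructs. Abundance, mapping quality and split pairs were drawn at random there, so the placement of reads among similar constructs was not tested.

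Several planned comparisons were left out. The overlap of constructs between the lines and the ratio per construct need a common numbering, which was not established: the alignment ends differed between the libraries for sgID-31, and for the other shared numbers they neither show nor exclude the same sgRNA. The gene lists (essential genes, growth suppressors, pluripotency, imprinted and germ cell genes, and transgene loci) need the target of each construct, which is not given in the sources used here. The series has 1 library per line, so no p-value was computed between the lines.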

Results

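The representation of guide RNAs was measured in 2 lines of mouse haploid embryonic stem cells, named 4B2N1-DP1 and 4B2N1-DP2 (DP1 and DP2 below). Haploid embryonic stem cells carry a single set of chromosomes, so that a change made by a guide RNA is not masked by a second allele. A single guide RNA (sgRNA) directs a Cas protein to a chosen DNA site, and a pool of cells carrying an sgRNA library can be read out by amplifying and sequencing the integrated sgRNA constructs. Genomic DNA from C57BL/6 cells was used, and each line was represented by 1 library. Each line therefore has no replicate, and no test between the lines was possible. The intervals below cover counting error only, and those over alignments treat the 2 ends of a pair as independent. The constructs were labelled sgID-1 upwards, and the genes that they target are not given in the sources used here. DP1 gave 23702568 aligned read ends from 11854072 read names, and DP2 gave 23897664 from 11948381. Of these, 9305738 alignments in DP1 and 20795400 in DP2 had a mapping quality of at least 1 and were counted. A mapping quality of 0 marks a read end that the aligner could not place on a single construct.

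The first question was how many sgRNA constructs were covered in each line. In DP1, 78 constructs, sgID-1 to sgID-78 without a gap in the numbering, each had at least 10 alignments. In DP2, 31 constructs, sgID-1 to sgID-31, again without a gap, passed the same limit. Construct names were taken from the alignments, so a construct without any alignment could not be listed. Passing the limit does not show that an sgRNA was present, since misplaced read ends also count. Of the pairs touching sgID-27 of DP1, only 24.1% had both ends on it. The median construct had 102358 alignments in DP1 and 356311 in DP2. By counted alignments, the least covered construct of DP2, sgID-20, still had 65881, whereas the lowest in DP1, sgID-27, had 76 and sgID-47 had 87. The 2 low constructs of DP1 were the only ones in either line under 100 counted alignments. When mapping quality was ignored, sgID-27 had 6048 alignments and sgID-47 had 89664, and no construct of DP1 had under 4015. At a mapping quality of at least 20, DP2 still had 31 constructs with 10 alignments or more, and DP1 had 71. The 7 constructs of DP1 that fell under that limit were sgID-19, sgID-27, sgID-47, sgID-53, sgID-56, sgID-61 and sgID-76. Among them, sgID-47, sgID-56 and sgID-61 had 0 of 6860691 alignments, which allows a share of up to 4.4e-05% of the alignments at that mapping quality. This does not limit their share in the library. When mapping quality was ignored, they had 89664, 152023 and 17894 alignments.

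**Figure D1:**
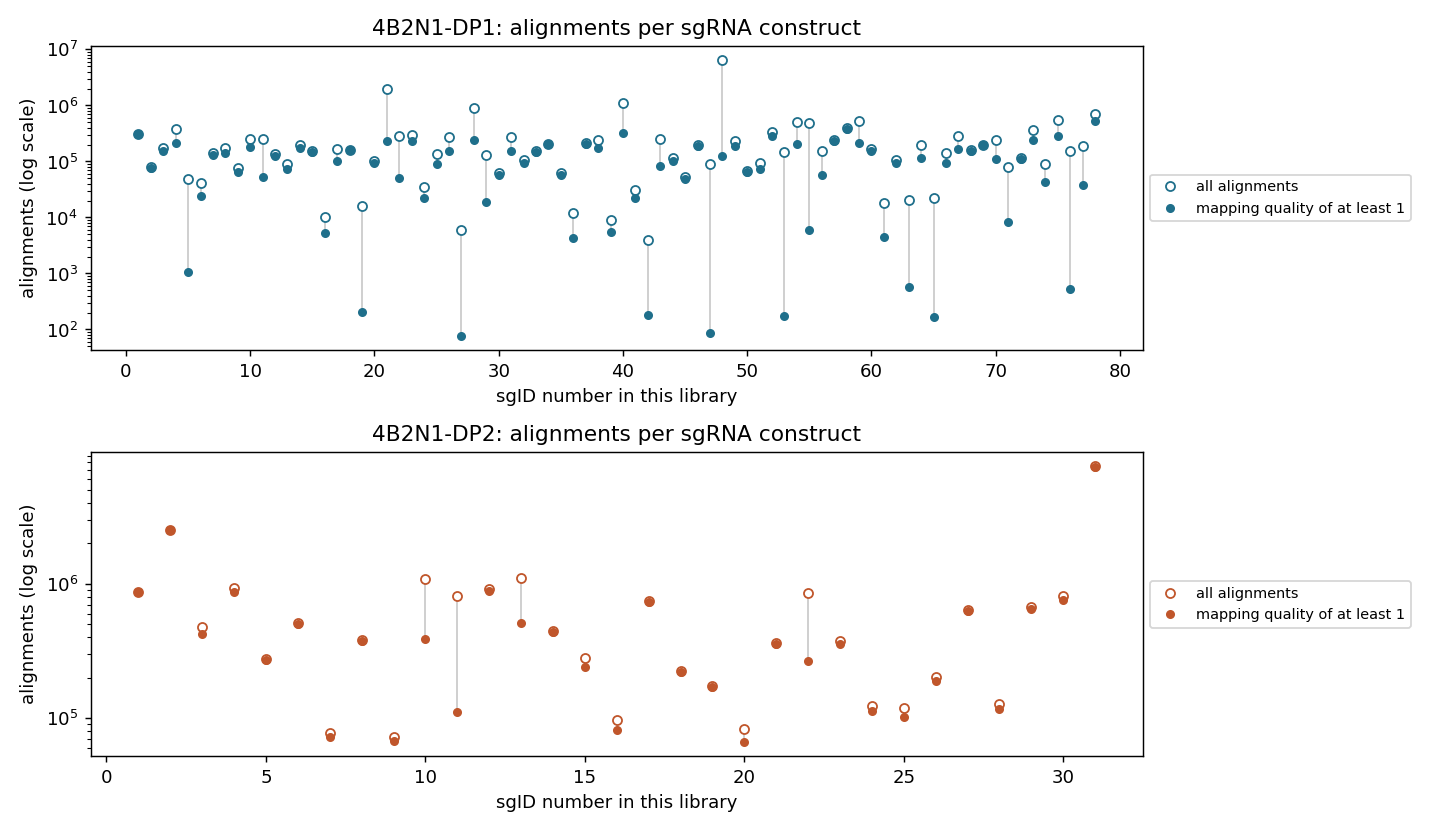
Alignments per sgRNA construct on a log axis, against construct number, for DP1 (upper panel, 78 constructs) and DP2 (lower panel, 31 constructs), 1 library each and without error bars. Open circles count all alignments, filled circles those with a mapping quality of at least 1, and a grey line joins both values of a construct; sgID-48 of DP1 drops from 6544166 to 125457, whereas sgID-31 of DP2 stays between 7531180 and 7457895.

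The second question was how the constructs were distributed within each line. DP2 was dominated by sgID-31, which held 35.9% of the counted alignments (Wilson 95% interval 35.84 to 35.88%), about 11.1 times the 3.23% that equal shares would give. sgID-31 was also the only construct of DP2 with an amplicon of 141 bases, against 147 for the others. The next construct of DP2 was sgID-2 with 12.0%. sgID-12 held 4.28%, sgID-4 held 4.19%, sgID-1 held 4.15% and sgID-30 held 3.63%. sgID-17 followed with 3.53%, sgID-29 with 3.15%, sgID-27 with 3.02% and sgID-13 with 2.47%. At a mapping quality of at least 20, sgID-1 held 0.212% and sgID-29 held 0.854%, and without a minimum sgID-13 held 4.62%; the other 7 shares moved by under 1.5 times. The 10 constructs together held 76.3% of the counted alignments of DP2, and 3 constructs were enough to reach 50% of them.

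In DP1 no construct held more than 5.67% of the counted alignments. That highest share belonged to sgID-78 (interval 5.66 to 5.69%), about 4.43 times the equal share of 1.28%. sgID-58 held 4.13%, sgID-40 held 3.40%, sgID-1 held 3.30%, sgID-75 held 3.04% and sgID-52 held 3.02%. sgID-28 and sgID-73 each held 2.58%, sgID-23 held 2.54% and sgID-57 held 2.51%. The leading 10 constructs of DP1 held 32.8% together, and 18 constructs were needed to reach 50% of the counted alignments. Over all alignments, the 10 most abundant held 57.7% in DP1 and 73.0% in DP2, and 7 of 78 and 4 of 31 constructs reached 50%. The leading 10 are a smaller part of 78 constructs than of 31, so their share does not show which line was more even. The ranking of DP1 depended on mapping quality. Without a minimum, sgID-78 held 2.99%, sgID-58 1.68%, sgID-1 1.33%, sgID-75 2.33% and sgID-52 1.41%. In that count sgID-73 held 1.54%, sgID-23 1.27% and sgID-57 1.00%, while sgID-40 and sgID-28 rose to 4.59% and 3.80%. At a minimum of 20, sgID-78 held 1.42%, sgID-58 held 0.118%, sgID-40 held 0.0033% and sgID-73 held 0.0013%. At a minimum of 30, sgID-1 held 0.0044% and sgID-57 held 0.0097%, while sgID-75 and sgID-52 led with 4.87% and 4.86%. Only 5 of the 10 constructs named for DP1 were also among the 10 most abundant when all alignments were counted, against 7 of 10 for DP2.

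The construct with the most alignments at mapping quality 0 was sgID-48 of DP1, chosen for description after its values were seen. It took 6544166 alignments, 27.6% of all alignments of DP1 (interval 27.59 to 27.63%), but 98.1% of them had a mapping quality of 0, and it held 1.35% of the counted alignments. The share at mapping quality 0 was higher still for 7 less abundant constructs of DP1, among them sgID-47 with 99.9%, sgID-53 with 99.9% and sgID-76 with 99.7%. sgID-21 of DP1 came second in number of such alignments, with 8.22% of all alignments, 88.3% of its own at mapping quality 0, and 2.45% of the counted alignments. A mapping quality of 0 was found in over 50% of the alignments for 27 of the 78 constructs of DP1 and for 4 of the 31 constructs of DP2, which were sgID-10, sgID-11, sgID-13 and sgID-22. For the whole library the share at mapping quality 0 was 60.7% in DP1 (interval 60.72 to 60.76%) and 13.0% in DP2 (interval 12.97 to 12.99%). At the other end of the scale, 2.77% of the alignments of DP1 and 52.8% of those of DP2 had the top mapping quality of 60.

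The third question was in which line the constructs were more evenly covered. By the Gini coefficient, which is 0 for equal shares, DP1 was more even than DP2, with 0.462 (multinomial 95% interval 0.4622 to 0.4627) against 0.614 (interval 0.6138 to 0.6142). The effective number of constructs, the exponential of the Shannon entropy, was 53.0 in DP1 and 13.3 in DP2, or 68.0% and 42.9% of the constructs present. The order by Gini coefficient turned when alignments of mapping quality 0 were included, at 0.622 in DP1 and 0.575 in DP2. The effective number was then 29.6 in DP1 and 15.2 in DP2, so it was still higher in DP1. As a share of the constructs present it turned as well, to 37.9% in DP1 and 49.1% in DP2. Without its most abundant construct, sgID-31, the Gini coefficient of DP2 was 0.463, against 0.449 in DP1 without sgID-78. The ratio of the 90th to the 10th percentile gave the opposite order to the Gini coefficient of the counted alignments, at 259.9 in DP1 (interval 247 to 273) and 10.7 in DP2 (interval 10.6 to 10.7). That ratio was set in DP1 by constructs with few counted alignments, and it was 53.8 over the 76 constructs with at least 100.

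**Figure D2:**
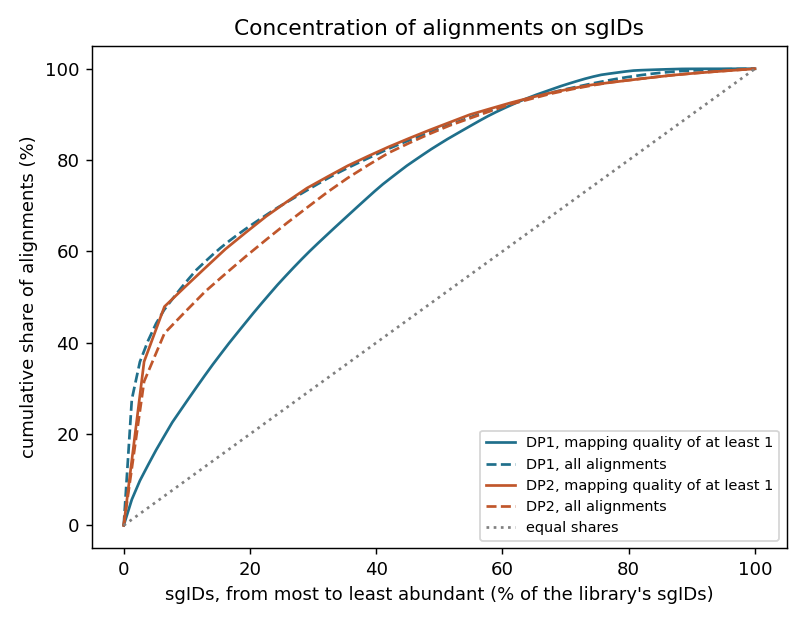
Cumulative share of alignments (%) against constructs ranked from most to least abundant (% of the library's constructs), for DP1 and DP2, counting alignments with a mapping quality of at least 1 (solid) or all alignments (dashed), with equal shares as a dotted diagonal. The first construct holds 5.67% in DP1 and 35.9% in DP2 of the counted alignments, and 27.6% and 31.5% of all alignments.

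The placement of both ends of a read pair was compared. Ends on different constructs are at odds with a read pair from a single construct, but ends on the same construct leave the assignment unchecked, since both read the same amplicon: sgID-76 of DP1 had 93.3% of its pairs with both ends on it although 99.7% of its alignments had a mapping quality of 0. In DP2, 0.0302% of 11939979 pairs had ends on different constructs (Wilson 95% interval 0.0292 to 0.0312%), and in DP1 4.35% of 11844105 pairs did (interval 4.34 to 4.37%). The 2 lines lay closer together where both ends had a mapping quality of at least 20. The share was then 0.0448% of 3397507 pairs in DP1 and 0.0264% of 9089594 pairs in DP2, still higher in DP1. Pairs with an unclear end are left out there, so a low share may follow from the limit itself. The most frequent combinations among the 515704 split pairs of DP1 were sgID-22 with sgID-28 (69042 pairs, 13.4%), sgID-28 with sgID-48 (48511 pairs, 9.41%) and sgID-26 with sgID-31 (39760 pairs, 7.71%). Every construct of DP2 had both ends on it for at least 99.71% of its pairs. In DP1, 8 constructs had both ends on them for under 50% of the pairs that touched them, namely sgID-16, sgID-19, sgID-27, sgID-36, sgID-39, sgID-42, sgID-61 and sgID-63. The lowest was sgID-42 with 4.22%, and these 8 constructs together took 0.401% of all alignments of DP1.

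**Figure D3:**
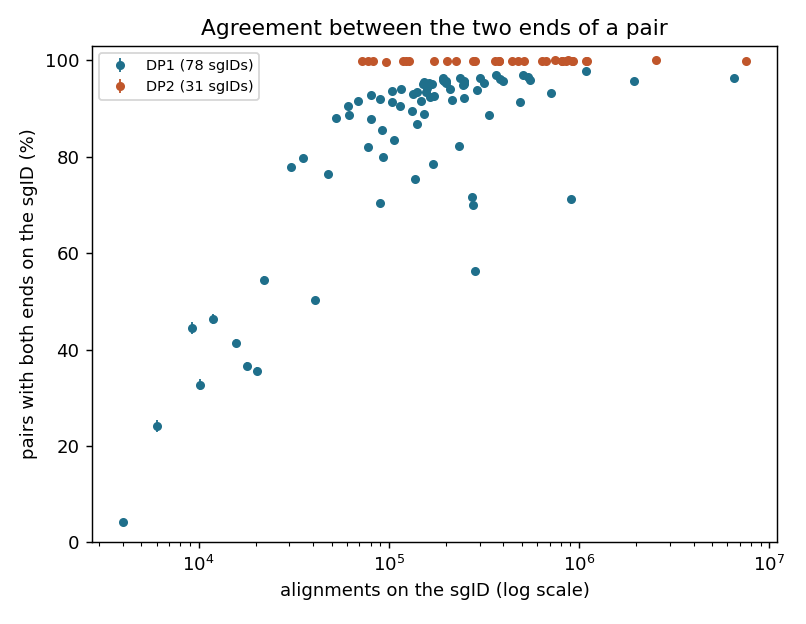
Share of read pairs with both ends on the construct (%, with Wilson 95% intervals) against the construct's number of alignments on a log axis, 78 constructs of DP1 and 31 of DP2. All constructs of DP2 lie at 99.71% or above, whereas the 8 constructs of DP1 under 50% had at most 20167 alignments.

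Each library was read in 2 sequencing lanes, which is a technical repeat of the same library. Between the lanes the share of a construct differed by a standard deviation of 0.06 on the log2 scale over the 78 constructs of DP1 and 0.02 over the 31 of DP2. All 31 constructs of DP2 and 74 of 78 in DP1 lay within 0.1 on that scale. The largest difference was that of sgID-42 of DP1, at -0.40 for lane 3 over lane 4. The chi-square of construct by lane was 14.4 times its degrees of freedom in DP1 and 15.0 times in DP2. The 2 ends of a pair entered as separate counts, which raises this value but not to that size. Lanes thus differed by more than counting error, and the intervals given here are narrower than the technical spread.

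A comparison of the lines construct by construct was not made, because it was not established that a number names the same sgRNA in both libraries and the construct sequences were not used here. Alignments over the whole amplified stretch began at base 196 of the reference in both lines. They ended most often at base 343 for 77 constructs of DP1 and at base 342 for 30 constructs of DP2, amplicons of 148 and 147 bases. The exceptions were sgID-78 of DP1 and sgID-31 of DP2, which both ended at base 336, an amplicon of 141 bases. Each was the last number of its line and had the most counted alignments there. Whether these 2 constructs are sgRNAs of the same kind as the others was not established. Of the 31 numbers present in both libraries, 0 had the same most frequent end, and 30 ended 1 base later in DP1. That 1-base offset is shared by all these constructs and does not show whether the sgRNAs differ. For sgID-31 the end was base 343 in DP1 and base 336 in DP2, so this number did not stand for amplicons of the same length. Whether any sgRNA was carried by both lines, and in what ratio, was therefore not measured here.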

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

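Of the tests reported here, only the relation between pair agreement and lane was set before its result was seen. The counts that the main comparison leaves out held most of DP1. Alignments with a mapping quality of 0 made up 60.7% of DP1 and 13.0% of DP2, and sgID-48 of DP1 alone had 6418709 of them. Without sgID-48 the share in DP1 was still 46.5%.

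For sgID-48, short alignments that miss the variable part of the construct do not account for the pattern, since 99.0% of its alignments of mapping quality 0 spanned the whole amplicon. A second reference sequence identical to sgID-48 is also argued against, because such a copy would leave no read with a clear placement, while 1.26% of its whole-amplicon alignments had a mapping quality of at least 20. What stays open are near-identical sequences within the DP1 set and reads of a construct outside that set, which cannot be told apart without the sequences: both allow the 96.3% of pairs touching sgID-48 that had both ends there. The number of constructs, 78 against 31, is the number of names among the alignments of each library. It does not show how many sgRNAs each line carried, which was not tested.

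The pairing of read ends by name is not used in the counts per construct, which take each end by itself. Pairs with ends on different constructs made up 4.35% of DP1 and 0.0302% of DP2. The constructs of DP1 with the lowest coverage were set against them in 2 rankings. Ranked by counted alignments, the 10 lowest (sgID-27, sgID-47, sgID-65, sgID-53, sgID-42, sgID-19, sgID-76, sgID-63, sgID-5 and sgID-36) had 76 to 4333 counted alignments, and the median share of pairs with both ends on the construct was 50.4% (4.22 to 93.3%), against 92.8% for the other 68. Whether their alignments came from other constructs cannot be told from that median, which lies between the limits set for either answer (under 50%, or 80% and more). Ranked by all alignments, the 10 lowest were sgID-42, sgID-27, sgID-39, sgID-16, sgID-36, sgID-19, sgID-61, sgID-63, sgID-65 and sgID-41, with 4015 to 30645 alignments. Their median share was 39.0%, against 92.9% for the other 68, so misplaced read ends from other constructs are a candidate source of many of their alignments. Some of these constructs are also in the first ranking. Low agreement was not confined to rare constructs: it was 56.2% for sgID-22 with 283263 alignments and 71.3% for sgID-28 with 900944. In DP2 the 10 lowest had a median of 99.9% in both rankings. Over the 78 constructs this share also went with the log2 ratio of lane 3 to lane 4 (Spearman's rho = 0.38, two-sided permutation p = 0.0008 with 100000 permutations, and Pearson's r = 0.66). More misplaced ends in lane 4 would give this direction. Without sgID-42 and sgID-27, the values farthest from the median, rho was 0.33 and r was 0.47. Of the 10 lowest by all alignments, 8 leaned to lane 4. That count says little by itself, since the median over the 78 constructs of DP1 also leaned to lane 4 (-0.009). The median log2 ratio was -0.084 for the 10 lowest and -0.008 for the other 68. The largest excess in lane 3 (0.07) was that of sgID-28, which took part in the most frequent split combinations. Split pairs were not counted per lane, so the source of the relation was not settled. Constructs are not independent replicates, rho was -0.02 over the 31 constructs of DP2, and a low number of cells carrying these sgRNAs stays open beside misplacement.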

How the results depend on the processing

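The number of covered constructs moved in DP1 but not in DP2. DP2 had 31 under every alternative run, and DP1 had 78 except for 76 at a limit of 100 alignments, 71 at a minimum mapping quality of 20, 63 at a minimum of 30, and 62 when both ends of a pair had to lie on the same construct at a mapping quality of at least 20. The order of the lines by Gini coefficient reversed under 3 alternatives: DP2 minus DP1 was 0.15 in the main count, -0.047 without a minimum, -0.055 when each distinct start, end and strand counted a single time, and -0.056 over pairs with both ends on a construct at any mapping quality. The sign of the difference in the share of the most abundant construct and in the percentile ratio was the same in all alternatives run. The equal share differs between the sets, however, and as a multiple of it the order of the most abundant construct reversed without a minimum. That multiple was 4.43 in DP1 and 11.1 in DP2 in the main count, and 21.5 and 9.77 without a minimum.

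The share of alignments counted was 39.3% in DP1 and 87.0% in DP2. It was 100% without a minimum, 28.9% and 76.1% at a minimum of 20, 24.2% and 74.7% at a minimum of 30, and 40.1% and 87.04% when each read name counted a single time. The Gini coefficient (0.462 in DP1, 0.614 in DP2) was 0.622 and 0.575 without a minimum, 0.499 and 0.657 at 20, 0.498 and 0.662 at 30, and 0.632 and 0.576 over pairs. It was 0.448 in DP1 at a limit of 100 alignments, and 0.613 in lane 3 and 0.615 in lane 4 for DP2. At a minimum of 20 and 30, the coefficient and the percentile ratio of DP1 cover only the 71 and 63 constructs that passed the limit. The least covered constructs of DP1 are thus left out of these values. The ratio of the 90th to the 10th percentile (259.9 and 10.7) was 22.9 and 11.3 without a minimum, 5529 and 11.9 at 20, 3278 and 12.2 at 30, and 33.9 and 11.4 over pairs. In DP1 it was 53.8 at a limit of 100, 290.2 in lane 3 and 235.4 in lane 4. Counting distinct positions gave Gini coefficients of 0.212 and 0.158 and ratios of 4.64 and 1.86, a setting in which an amplicon with fixed ends has few positions to count by construction. The most abundant construct of DP1 (sgID-78, 5.67%) became sgID-48 with 27.6% without a minimum and 28.3% over pairs, sgID-1 with 4.46% at 20, and sgID-75 with 4.87% at 30. In DP2 it was sgID-31 throughout, at 35.9% in the main count, 31.51% without a minimum, 31.53% over pairs, 39.5% at 20, 40.0% at 30, 35.7% in lane 3 and 36.0% in lane 4. Of the shares of the named constructs under the 3 alternatives of mapping quality, 20 of 30 moved by over 1.5 times in DP1 and 5 of 30 in DP2. Why mapping quality differs between the sets was not settled, and the cause was not tested beyond sgID-48. Thinning DP2 to the depth of DP1 was run for the number of covered constructs, the Gini coefficient and the percentile ratio, and moved none of these for DP2 beyond counting error; DP1 is not thinned in this setting. The lack of a second library per line limits all comparisons. The lane and pair settings were chosen after seeing the data. Merging of neighbouring positions was not run, since the references were constructs and not chromosomes, and the alternatives for shared constructs, ratios and gene lists were not run because those results were left out, with no common numbering established and no target genes. No paired analysis was possible because each line has 1 library.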

Other observations

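Long alignments were the rule in both lines: 97.5% of the alignments of DP1 and of DP2 spanned the amplicon. Among forward alignments that stopped short, the most frequent last base was 249 in DP1 (13.8% of 215669) and 250 in DP2 (18.9% of 235822). Among reverse alignments that stopped short, the most frequent first base was 268 in DP1 (16.0% of 263856) and 271 in DP2 (9.75% of 257646). The stretch between these positions ran from base 250 to 267 in DP1 and from base 251 to 270 in DP2, which is 18 and 20 bases.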
